A study of Mus musculus with 3 samples.

How the data were processed

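Neural progenitors from postnatal day 1 mice were grown with 20 ng/mL epidermal growth factor, plated at 50000 cells and cultured for 16 h before electroporation, and 10000 cells per condition were loaded for droplet sequencing of transcript 3' ends, per the labels' protocols. No cargo is named there. The deposited counts were whole UMI counts per gene and barcode for 32285 genes. Cell Ranger 6, Seurat 4.0.4 and the build GRCm38 are named in the submitters' processing notes, while the matrices carry Cell Ranger 4, per the file headers. The annotation release was not given in the sources used here. The matrices held all barcodes, from 1591037 to 1726139 per library, including empty ones, so no cell filter of the authors could be used.

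Before the data were examined, the groups, the filters, 24 gene lists, 12 marker lists, the rule for named genes and most alternatives were fixed. A barcode was called a cell when its UMIs reached 1/10 of the 99th percentile of the library's top 3000 barcodes. Cells needed at least 500 genes and at most 20% mitochondrial UMIs. Scrublet with an expected rate of 0.06 marked 1 control, 2 bulk and 1 localized cell as doublets, under 0.5% of cells, so the doublet caller has not worked and doublets remain. UMIs outside called barcodes made up 16.9% of control, 12.8% of bulk and 9.28% of localized electroporation.

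UMIs were summed over kept cells, giving 61841508, 74767509 and 75983851 UMIs in control, bulk and localized electroporation, and scaled to an equal total per library (CPM). Log2 ratios used a pseudocount of 1 CPM, which lowers the ratios of genes near 0. Counts of 2-fold genes took genes of at least 20 CPM in either library, and lists took members of at least 5 CPM. Intervals are exact Poisson for sums and exact Clopper-Pearson for shares, at 95%, and cover counting error only. The interval of a library's median UMIs comes from its ranked cell values and covers the spread over cells only. A list stood apart when its median lay outside the central 95% of 10000 random lists of the same size matched on mean expression, which describes these libraries and is not a test. Named genes were the 12 highest and 12 lowest ratios per comparison among genes of at least 50 CPM, without predicted, Riken and ribosomal protein genes, and up to 4 members per list with the largest ratios. Oasl2, Junb, Ifnb1, Ifna4, Hes1, Ccl5, Cdkn1a and the transfer RNA synthetase genes other than Cars lie outside this rule. They were chosen after their values were seen, as were the set of 5 interferon-response genes and the limit of 25000 UMIs. Some genes that this rule takes are not reported here. The second Ddit3 gene of the files had 0 UMIs. Coordinates come from GENCODE vM21 on GRCm38 by gene identifier.

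Cells were clustered on log-normalised counts of 2000 variable genes per library, centred and scaled within each library, with 30 principal components, 15 neighbours and Leiden resolution 0.5. Clusters were named from the fixed markers. The naming rule was revised once after its output was seen. The first rule tried only the marker set with the highest mean ratio and left cluster 5 unnamed, although Lhfpl3 and Pdgfra led it. The revised rule took the set with most genes among the cluster's 10 leading genes. In the clustering fixed beforehand the revision changed the oligodendrocyte precursor-like share from 14.0% to 21.2% of control, from 7.11% to 14.4% of bulk and from 13.2% to 16.9% of localized cells. In the clustering without differing genes, used for the comparison of classes and itself added after the data were seen, both rules gave the same shares. That clustering left out 2958 genes that differed at least 1.5-fold between libraries within a cluster.

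Depth as a cause of the interferon-response ratios was first tested on list members above the CPM minimum. That test was replaced by 1 over all 18 members without a minimum, because most members met the minimum through the bulk library alone. Free RNA in control was first weighed by the ratio of levels in barcodes of 10 to 100 UMIs to those in cells, which decided nothing. Shares of 10%, 20%, 30%, 50%, 60%, 70%, 80% and 90% of control UMIs were then taken away with that profile, and 50% was taken for the test after all of them had been looked at. The test was set for both comparisons with control together and was split by comparison once the bulk interval was seen to include 0. With 30% taken away, which 8 genes were too low to allow, the bulk median was -0.53 (-0.95 to -0.031), and with 90% it was 0.23. Intervals of these medians come from resampling the list members and do not cover variation between libraries.

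For shares of cells and phases, each cell was thinned to 4500 UMIs, which left out 459 control, 0 bulk and 93 localized cells. On sums simulated from these libraries for bulk over control, with 5434 genes, 67 of 67 genes changed 3-fold passed 2-fold, 0 of 67 changed 1.5-fold did, and 0 of 5235 unchanged genes did. Of 200 random unchanged lists, 2 stood apart. Only counting error was drawn there, which is small at these totals, so these values say nothing on variation between libraries. Python 3.11.15, Scanpy 1.11.5, SciPy 1.17.1, NumPy 2.4.6 and leidenalg 0.10.2 were used. Alternatives varied the cell call, the gene, mitochondrial and doublet filters, the scaling, including median-of-ratios size factors computed over the 3 sums, the pseudocount, the CPM minimum, free RNA, the cells used and the clustering. The cell calls applied to cell quality values, the settings of cells of 6000 to 20000 UMIs, of the highest 6% of Scrublet scores left out, and the class settings without differing genes, with 2000 UMIs in every library or with the first naming rule were chosen after the data were seen.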

Results

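Single-cell RNA sequencing was done on mouse neural progenitors, cells that can form neurons and glia, grown as neurospheres from brains of postnatal day 1 mice and then plated. The 3 libraries were a control, cells given bulk electroporation in a Nucleofector, and cells given localized electroporation, in which 400 pulses of 20 V were applied on the device the cells had been plated on. Cells were collected 4 h after treatment. Each group had 1 library, so no difference below has a replicate check and no test was possible. Intervals of sums and shares cover counting error only. Intervals of medians cover the spread over cells or over list members. No interval covers variation between libraries. The deposited matrices held 74429007 UMIs (unique molecules counted) in control, 85743257 in bulk electroporation and 83803032 in localized electroporation.

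After filtering, 6114 control cells, 4953 bulk cells and 6248 localized cells were kept. Their median depth was 9530 UMIs (95% interval 9402 to 9647) in control, 12363 (12202 to 12545) in bulk and 11032 (10894 to 11171) in localized electroporation. Median genes per cell were 2815.5, 3433 and 3266.5 in the same order, and 1788, 1864 and 1884 after each cell was thinned to 4500 UMIs. The median mitochondrial share was 3.44% in control, 4.12% in bulk and 3.42% in localized electroporation. Cells above 25000 UMIs made up 1.11% of control (exact binomial interval 0.865 to 1.41), 10.8% of bulk (9.91 to 11.7) and 2.75% of localized cells (2.36 to 3.19). The minimum of UMIs that called a cell was 2799.7 in control, 5885.8 in bulk and 3596.3 in localized electroporation, so shallow bulk cells were left out more often.

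The first comparison asked how bulk electroporation differed from control. Transcripts of the interferon response, the antiviral programme of the cell, were far higher in the bulk library, while genes of the integrated stress response, cholesterol synthesis and small nucleolar RNA hosts were lower. Cxcl10, a chemokine gene, stood at 590 CPM (UMIs scaled to the same total in every library; exact Poisson interval 584 to 595) in bulk and 3.49 CPM (3.04 to 3.99) in control, a log2 ratio of 7.04. The largest negative ratio among the named genes was that of Chac1, a glutathione-degrading enzyme gene, at 14.8 CPM in bulk and 71.9 CPM in control. Of 5820 genes with at least 20 CPM in either library, 39 were at least 2-fold higher and 34 at least 2-fold lower in bulk.

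Of the 18 interferon-response genes, 14 were measured, all 14 were higher in bulk and 10 were at least 2-fold higher. The minimum of 5 CPM was met in control by 3 of them, while the other 11 entered through the bulk library and were higher by that rule. Without a minimum all 18 were higher in bulk. The median log2 ratio of the 14 genes, 1.87, lay at percentile 100 of 10000 random lists matched on expression. Isg15, a ubiquitin-like antiviral gene, had a log2 ratio of 6.34, Ifit1 6.13, Rsad2 6.01, Ifit3 4.37 and Oasl2 4.30, and Oasl1, outside the list, had 5.80. Cxcl10, of the NF-kB and inflammatory list (ENSMUSG00000034855, GRCm38 chromosome 5, 92346638 to 92348889, minus strand, protein coding), had 44108 UMIs in bulk cells and 216 in control cells. After thinning, 35.0% of bulk cells held a Cxcl10 UMI, against 0.707% of control and 0.97% of localized cells. Without thinning the shares were 48.9%, 1.11% and 2.24%. A UMI of Cxcl10, Isg15, Ifit1, Rsad2 or Oasl1 was found in 41.7% of thinned bulk cells (40.3 to 43.1), against 1.22% of control and 1.49% of localized cells, a set of 5 genes chosen after their values were seen, of which Cxcl10 and Oasl1 lie outside the interferon list. The 5 genes together stood at 1108 CPM in bulk cells and at 670 CPM in bulk barcodes of 10 to 100 UMIs, so free RNA may add to the bulk shares. Those barcodes, 93391 in number, held 2456 UMIs of the 5 genes, fewer UMIs than barcodes, while the 4953 bulk cells held 82849. Free RNA at that load per droplet would reach few bulk cells, but the load in droplets with cells was not measured. The 10% of bulk cells richest in these transcripts held 77.7% of their UMIs. The thinned share was 24.6% in bulk cells of up to 7500 UMIs and 73.9% in those above 25000 UMIs. No Ifnb1 UMI was found in any library, which by a limit of 3 UMIs allows up to 0.0401 CPM in bulk cells. Ifna4, another interferon gene, had 2 UMIs, in 2 bulk cells, and 0 in control and in localized cells.

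**Figure D1:**
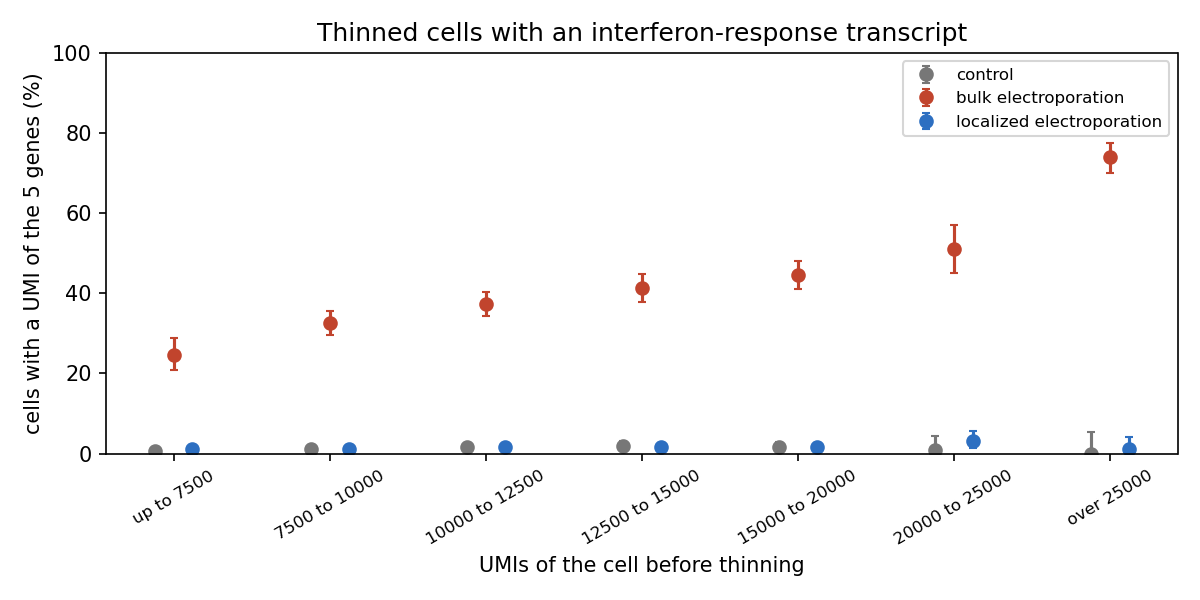
Share of cells, thinned to 4500 UMIs, with a UMI of Cxcl10, Isg15, Ifit1, Rsad2 or Oasl1 (vertical axis, percent) by the cell's UMIs before thinning (horizontal axis), for the 3 libraries, with exact binomial 95% intervals. Bulk cells go from 24.6% to 73.9%.

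Integrated stress response genes, which follow the translation-linked factor ATF4, were lower in bulk. Of 20 measured, 17 had negative ratios, 5 were at least 2-fold lower and the median log2 ratio was -0.60 (percentile 0). Chac1 had a log2 ratio of -2.21, Ddit3 -2.15, Trib3 -1.98 and Stc2 -1.36. Ddit3, which encodes the factor CHOP (ENSMUSG00000025408, GRCm38 chromosome 10, 127290774 to 127296288, plus strand), stood at 48.0 CPM (46.5 to 49.6) in bulk and 216 CPM (213 to 220) in control. All 19 cholesterol synthesis genes were lower in bulk, with a median of -0.67 (percentile 0), among them Msmo1 at -1.37 and Insig1 at -1.30. Of 11 measured small nucleolar RNA host genes, 9 were lower, with a median of -0.49, Snhg5 at -1.84 and Snhg1 at -1.58. Immediate early genes had a median of -0.37, with Atf3 at -1.47 and Fosl2 at -1.11.

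Smaller list medians also lay outside the random lists. The p53 targets were higher in bulk with a median of 0.23 (percentile 99.1), 16 of 19 above 0 and Trp53inp1 at 1.10, although Gdf15 stood at -1.95 and Gadd45a at -1.09. NRF2 targets had a median of 0.26 with Srxn1 at 1.17, intrinsic apoptosis genes 0.26 with Mcl1 at 0.73, G2/M genes 0.23, membrane repair genes 0.20 with Anxa2 at 1.52, and mitochondrially encoded genes 0.22. Ribosome biogenesis genes had a median of -0.20, and genes of the endoplasmic reticulum unfolded protein response -0.10 with Herpud1 at -1.13. The cytosolic heat shock list did not stand apart (median -0.03, percentile 10.3), with Hspa1a at -1.83 and Bag3 at 1.12 going opposite ways. Lmna, a nuclear lamina gene, had a log2 ratio of 1.32 and Id2 -1.73. Hes5 had -1.56 against its list of neural stem cell identity genes, which had a median of 0.18 (percentile 98.6) with 12 of 18 above 0. Under median-of-ratios scaling the median of all genes moved by -0.15, and the higher genes went from 53.4% to 32.9% of those past 2-fold, while the p53 median was 0.092. Oligodendrocyte precursor markers had a median of -0.82 in bulk over control, but 0.22 in the largest cluster. Among cells of 6000 to 20000 UMIs, a setting chosen after the data were seen, it was 0.19. The minimum that called a cell was 5885.8 UMIs in bulk and 2799.7 in control, so shallow precursor cells may be missing from bulk.

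**Figure D2:**
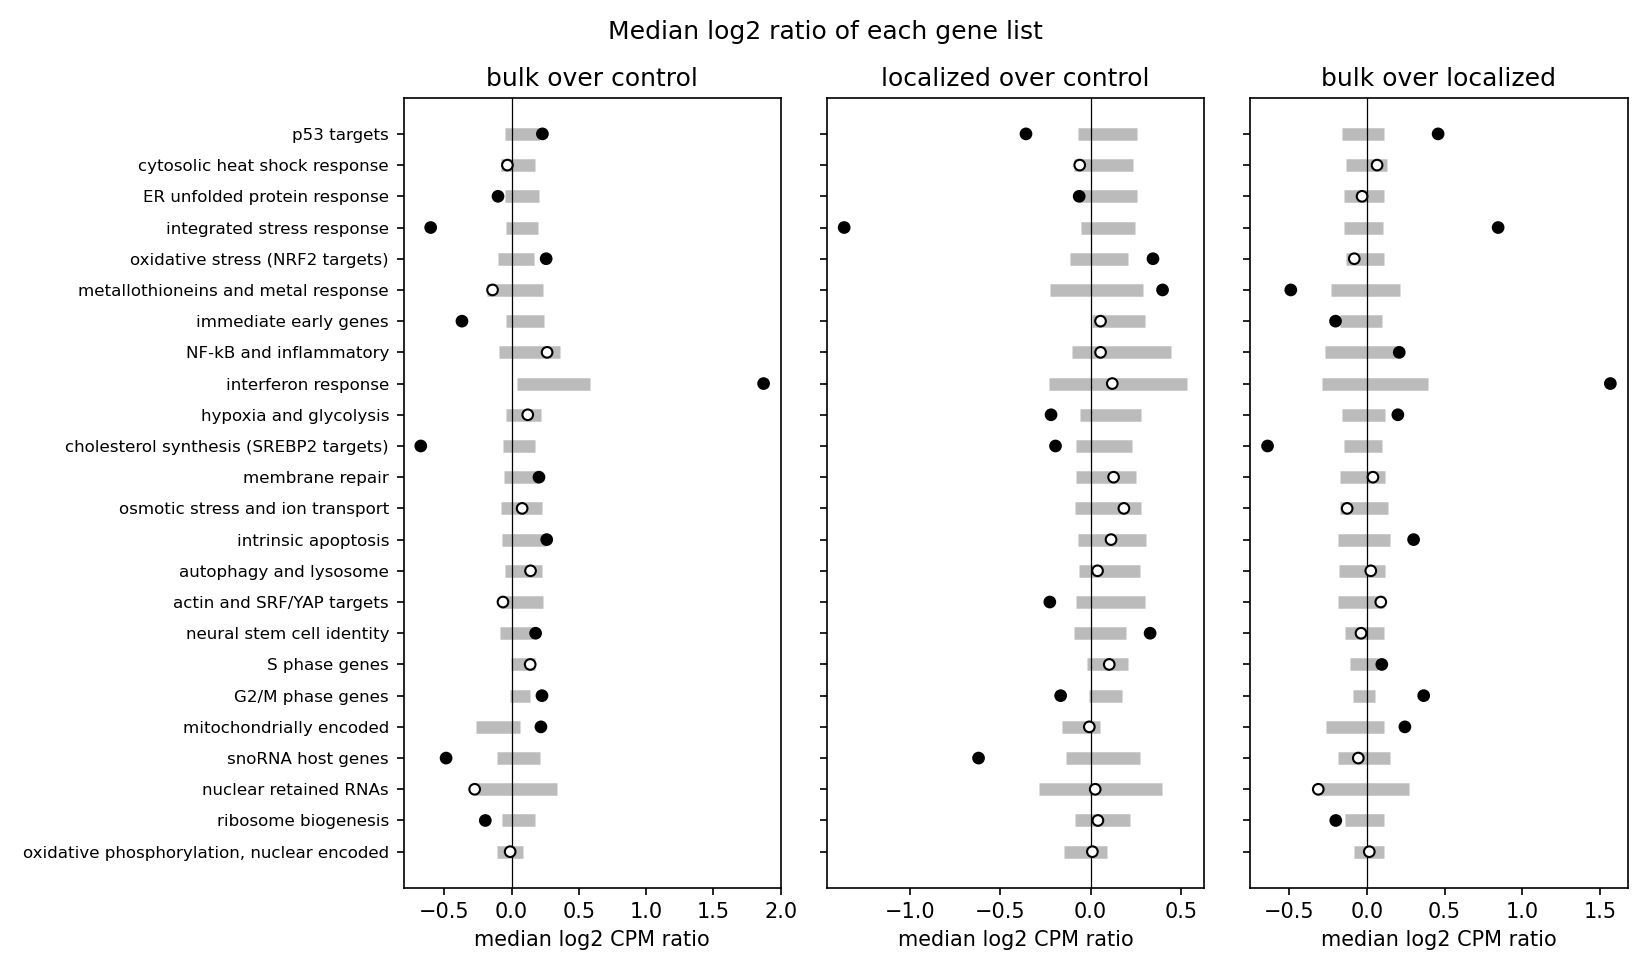
Median log2 CPM ratio of each of the 24 fixed gene lists (horizontal axis) in the 3 comparisons. Grey bars span the central 95% of 10000 matched random lists and filled points lie outside them, except NF-kB and inflammatory genes in bulk over localized electroporation, which lie on the limit. The interferon median is 1.87 in bulk over control, and the integrated stress response median is -1.37 in localized over control.

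The second comparison asked how localized electroporation differed from control. Integrated stress response genes were lower in the localized library by a larger ratio than in bulk, and interferon-response genes did not stand apart. The immediate early gene Fos and the heme oxygenase gene Hmox1 were higher, as were 8 of 11 astrocyte markers and 14 of 18 neural stem cell identity genes. Of 5902 eligible genes, 72 were at least 2-fold higher and 60 at least 2-fold lower. Cells lay on the device in localized electroporation, and the labels do not say where control cells lay, so device and pulses cannot be told apart.

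All 20 integrated stress response genes were lower in the localized library and 15 were at least 2-fold lower, with a median log2 ratio of -1.37 (percentile 0). Chac1 (ENSMUSG00000027313, GRCm38 chromosome 2, 119351229 to 119354381, plus strand) stood at 1.80 CPM (1.51 to 2.13) against 71.9 CPM in control, from 137 and 4445 UMIs, a log2 ratio of -4.70. Trib3 had -4.21, Ddit3 -3.39, Nupr1 -2.42, Mthfd2 -2.33, Sesn2 -1.84 and Atf4 itself -1.64. After thinning, 46.9% of control cells held a Ddit3 UMI, against 13.7% of bulk and 7.77% of localized cells, and without thinning the shares were 59.8%, 28.8% and 17.2%. No cell class here should lack Ddit3, so the part of these shares due to free RNA is not known; over the 20 list members the control's barcodes of 10 to 100 UMIs stood at a median of 0.919 times the cell level. Small nucleolar RNA hosts had a median of -0.62 with Snhg12 at -1.99. The p53 targets had a median of -0.36 (percentile 0), with 13 of 19 lower, Gdf15 at -3.30, Gadd45a at -1.51 and Btg2 at 1.10. Cholesterol synthesis genes had a median of -0.19, actin and SRF/YAP targets -0.23 and hypoxia genes -0.22 with Vegfa at -1.74. Unfolded protein response genes had -0.06, and 0.0046 after free RNA was subtracted.

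Among genes higher in the localized library, S100a6 had a log2 ratio of 2.13, Pla2g7 2.03, Ndrg2 2.02, Apoe, a lipid carrier of astrocytes, 1.91, Hmox1 1.71, Ttyh1 1.52, Mat2a 1.44 and Aldh1a3 1.39. Astrocyte markers had a median of 0.56 (percentile 99.99), with 3 of 11 at least 2-fold higher, Gfap at 3.14 and Aqp4 at 1.06, but a median of -0.041 in the largest cluster. Neural stem cell identity genes had a median of 0.33 (0.18 in bulk over control), with 1 at least 2-fold higher, the Notch target Hes5 at 1.10, Id1 at 0.99 and Hes1 at -0.69. Oligodendrocyte precursor markers had a median of 0.63 with Sox10 at 1.33. Immediate early genes had a median of 0.05 that did not stand apart, with Fosb at 2.29, Fos at 1.58 and Junb at 1.56, and Atf3 at -3.25 and Klf4 at -2.30. NRF2 targets had a median of 0.35 with Srxn1 at 1.95, and metal response genes 0.40. G2/M genes had a median of -0.17 with Top2a at -0.56. The 4 measured interferon genes had a median of 0.12 (percentile 38.5), and -0.06 under median-of-ratios scaling. Median-of-ratios scaling moved the median of all genes by -0.21, and the higher genes went from 54.5% to 31.6% of those past 2-fold. Positive medians nearer to 0 than this shift can change sign with the scaling.

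**Figure D3:**
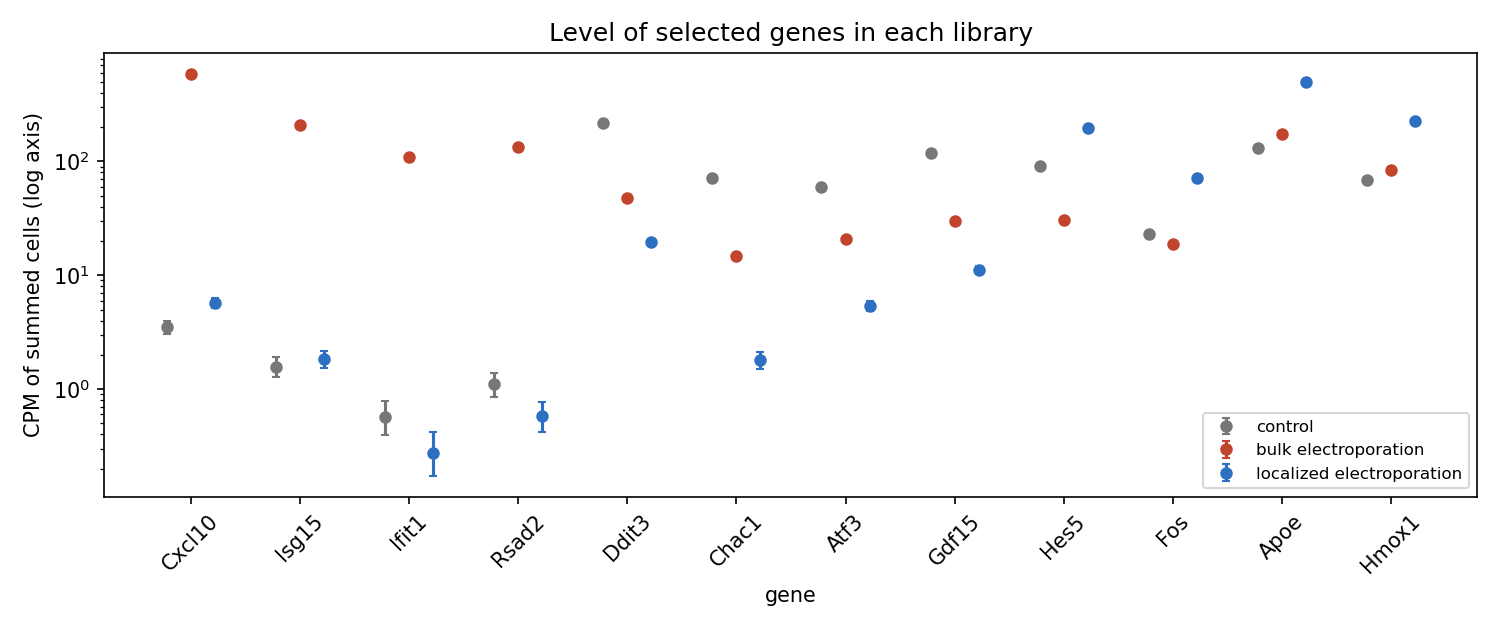
CPM of selected genes (horizontal axis) in the summed cells of each library (vertical axis, log scale), with exact Poisson 95% intervals, most smaller than the points. Cxcl10 is at 590 CPM in bulk, Ddit3 at 216 CPM in control and Apoe at 496 CPM in localized electroporation.

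The third comparison set the electroporation methods against each other. The bulk library was higher in interferon-response, integrated stress response and p53 target genes, and lower in cholesterol synthesis and oligodendrocyte precursor genes, while astrocyte markers went both ways around a negative median. Of 6010 eligible genes, 62 were at least 2-fold higher in bulk and 40 at least 2-fold lower. Interferon genes had a median of 1.56, with Rsad2 at 6.43. Of the 14 measured, 10 entered through the bulk library alone and were higher by that rule. The other 4 had ratios from 0.42 to 1.57, and the median of all 18 without a minimum was 1.17. Integrated stress response genes had a median of 0.84, 19 of 20 being higher in bulk, with Chac1 at 2.49, Trib3 at 2.23 and Sesn2 at 1.49. The p53 targets had a median of 0.46 (percentile 100), with Gdf15 and Bbc3 at 1.35, Eda2r at 1.10 and Ccng1 at 1.01. G2/M genes had a median of 0.37, intrinsic apoptosis genes 0.30, mitochondrially encoded genes 0.25 and hypoxia genes 0.20. Rab3b had 1.51, Ecrg4 1.41 and Acta2, a smooth muscle actin gene, 1.46.

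Hes5 (ENSMUSG00000048001, GRCm38 chromosome 4, 154960923 to 154962371, plus strand) had the lowest ratio of bulk over localized electroporation among the named genes, -2.66, with 30.3 CPM (29.1 to 31.6) in bulk, 91.2 CPM in control and 197 CPM (194 to 200) in localized electroporation. Pla2g7 had -2.04, Fos -1.87, Id2 -1.82, Id1 -1.80, Ndrg2 -1.66, Apoe -1.51, Col11a1 -1.47 and Hmox1 -1.44. All 19 cholesterol synthesis genes were lower in bulk, with a median of -0.64. Oligodendrocyte precursor markers had a median of -0.99 with Gpr17 at -2.35, oligodendrocyte markers -1.08 and metal response genes -0.49. Cells of the precursor-like cluster 4, described below, had a median of 6402 UMIs. The call minimum was 5885.8 UMIs in bulk and 3596.3 in localized electroporation, so the bulk call may have left out more such cells. Astrocyte markers had a median of -0.28 over all cells, with 7 of 11 below 0 and Clu at 1.07. In the largest cluster the median of the astrocyte markers was 0.076. Neural stem cell identity (-0.037), heat shock (0.07), NRF2 (-0.08) and nuclear-encoded oxidative phosphorylation genes (0.02) did not stand apart.

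Of 5641 genes measured in both comparisons with control, 21 were at least 2-fold lower in both treated libraries, among them Chac1, Ddit3, Atf3, Gdf15, Snhg1 and Vegfa, and 6 were higher in both. Independent lists would share 0.362 and 0.0945 genes. Genes had to meet the CPM minimum in each comparison, so genes low in control entered only if both treated libraries reached it. This kept 13 of the 39 genes higher in bulk and 41 of the 72 higher in localized electroporation. The 34 and 60 lower genes all stayed. The rule thus favours overlap among higher genes, and the excess of 6 over 0.0945 is built in to an unknown extent. In 100 simulations, treated sums drawn from the control's own levels shared 0 genes past 2-fold with each other. The control was kept as observed there, so error in it was not simulated. The 0 therefore says nothing on overlap that comes through the shared control. The control library is common to both comparisons, so part of the overlap may come from that library. Hes5 alone was 2-fold lower in bulk and 2-fold higher in localized electroporation.

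Other fixed lists gave small or uncertain medians. NF-kB and inflammatory genes, with 7 measured, had 0.26 in bulk over control and 0.06 in localized over control, neither apart, and 0.21 in bulk over localized electroporation, on the upper limit of the random lists. Cxcl10 belonged to this list and had by far its largest ratios in bulk, 7.04 over control and 6.46 over localized electroporation, and Relb had 1.12 in the latter. S phase genes had 0.14 and 0.10 over control, neither apart, with Ccne2 at 1.14 and 1.12, and 0.10 in bulk over localized electroporation, apart. Neural stem or progenitor markers had 0.21 and 0.35 over control, both apart, and dividing markers 0.16, not apart, and -0.26, apart, with 0.40, apart, in bulk over localized electroporation. Transit amplifying progenitor markers, with 3 measured, had 0.37 in bulk over control, apart, and 0.09 in localized over control, not apart. Lists of osmotic stress and ion transport (0.08 and 0.18 over control) and of autophagy and lysosome (0.14 and 0.04) did not stand apart in any comparison. The same held for nuclear-encoded oxidative phosphorylation (-0.01 and 0.01) and neuron markers (0.07 and -0.09). It also held for nuclear retained RNAs (-0.27, on the lower limit of the random lists, and 0.03, with Neat1 at -1.01 in bulk). Oligodendrocyte markers had 0.97 in localized over control, from 3 measured genes. Markers of ependymal, microglia or macrophage, endothelial, mural or fibroblast and erythroid cells had at most 1 measured member, so no median was given.

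The cells formed 8 clusters. Cluster 1 was astrocyte-like (Apoe, Gfap), cluster 3 dividing-like (Cdc20, Cenpf), clusters 4 and 5 oligodendrocyte precursor-like (Lhfpl3, Pdgfra) and cluster 7 oligodendrocyte-like (Mbp, Bcas1). Over all cells a Gfap UMI was found in 45 control, 93 bulk and 472 localized cells. Cluster 1 held 983 control and 868 bulk cells, so most of these had no Gfap UMI. Its 10 leading genes differed by a median of 4.29-fold between libraries within the cluster. Clusters 0, 2 and 6, led by histone genes, by Ier3 and Klf10, and by interferon-response genes, stayed unnamed. Of the 774 cells of cluster 6, 591 were bulk cells, so it may stand for that library and not for a cell type. Integrated stress response medians were negative in each of the 6 clusters with at least 100 cells per library, from -1.03 to -0.22 in bulk and from -1.67 to -1.05 in localized electroporation over control. Genes that defined the clusters differed between libraries, so class sizes were compared only after clustering without such genes. Oligodendrocyte precursor-like cells then made up 19.0% of control, 13.8% (12.9 to 14.8) of bulk and 16.3% (15.4 to 17.3) of localized cells. With a minimum of 2000 UMIs in every library they made up 13.2% (12.4 to 14.1), 11.5% (10.7 to 12.4) and 12.6% (11.8 to 13.5), from 1 cluster in place of 2. With that minimum and all variable genes, which gave 2 clusters, they made up 21.7%, 19.4% and 18.6% (17.7 to 19.6), so which treated library had fewer depended on the setting. With the minimum of 2000 UMIs and without differing genes, astrocyte-like cells made up 17.8% (16.9 to 18.8) of control, 18.8% (17.8 to 19.8) of bulk and 22.5% (21.5 to 23.6) of localized cells, while without differing genes at each library's own minimum no cluster had that name. Values not centred per library gave 8.52%, 14.9% and 42.5%. After thinning, 39.5% of control (38.2 to 40.7), 45.4% of bulk (44.1 to 46.8) and 29.6% of localized cells (28.4 to 30.7) were called G2/M, and without thinning 40.4%, 47.7% and 30.2%. Thinned S shares were 12.4% of control, 11.9% of bulk and 17.2% (16.3 to 18.2) of localized cells, an order of the treated libraries opposite to that of the S phase list, and thinned G1 shares 48.1%, 42.7% and 53.2%. Free RNA could differ between libraries in these calls, which alone do not show cycling.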

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

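All tests of explanations in this part were chosen after the results were seen, except the test of total UMIs. That test still rests on the limit of 25000 UMIs, which was itself chosen after the values were seen. Interferon-response transcripts also appeared in barcodes of 10 to 100 UMIs, which were not called cells and served only as the free RNA profile. There Cxcl10, Isg15, Ifit1, Rsad2 and Oasl1 together stood at 670 CPM (643 to 697) in bulk, 42.1 CPM (35.1 to 50.1) in control and 56.0 CPM in localized electroporation. In cells the same genes stood at 1108 CPM in bulk, 6.95 CPM in control and 8.59 CPM in localized electroporation.

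Several lists that stood apart over all cells had cluster medians of opposite sign, and the differences between clusters were not tested. Unfolded protein response medians in localized over control went from -0.30 to 0.21. Immediate early medians in bulk over control went from -0.58 to 0.14. Hypoxia medians in localized over control went from -0.30 to 0.19.

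Interferon-response genes were higher in bulk. Of 1409 bulk cells with at least 2 thinned UMIs of the 5 genes, 0.213% (0.0439 to 0.621) held a microglia or macrophage marker, which argues against immune cells as the carriers. The 5 genes stood 1.65 times higher in bulk cells than in the low barcodes, which argues against free RNA as their whole source. Among cells of 6000 to 20000 UMIs the median over all 18 list members without a CPM minimum was 1.21 (0.65 to 2.75), which argues against depth. The treatment, its handling and any cargo stay open and untested, since each group had 1 library.

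Integrated stress response genes were higher in control. The medians among cells of 6000 to 20000 UMIs were -0.90 in bulk and -1.36 in localized over control, which argues against depth, and the highest cluster median was -0.22 in bulk, which argues against the mix of clusters. With 50% of control UMIs taken away as free RNA with the profile of barcodes of 10 to 100 UMIs, a share that 25 genes were too low in control cells to allow, the localized median was -0.93 (-1.58 to -0.63), which argues against free RNA of that profile as the whole cause there. In bulk over control that median was -0.40 (-0.83 to 0.13), an interval that includes 0, so the median alone does not decide there. The 25 genes too low for it argue against a 50% share of that profile in control cells. Members stood at a median of 0.919 (0.702 to 1.09) times their cell level in barcodes of 10 to 100 UMIs, an interval that includes equal levels. With 10%, 20% and 30% taken away the bulk intervals stayed below 0, at -0.91 to -0.14, -0.93 to -0.067 and -0.95 to -0.031. These values argue against free RNA of those shares as the whole cause. The share present in control cells was not estimated. Control handling or substrate and the treatments themselves stay open and untested.

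More bulk cells exceeded 25000 UMIs. After cell UMIs were scaled to the control's median, 5.83% (5.20 to 6.52) of bulk cells still did, against 1.11% of control, which argues against total UMIs alone. Of 533 such bulk cells, 1 (0.188%, 0.00475 to 1.04) held both precursor and astrocyte genes, against 0.872% of random pairs of bulk cells, so droplets of unlike cells cannot be told apart by this test. In localized electroporation 13.4% of such cells held both sets, against 5.02% of random pairs. Among cells above 25000 UMIs, 73.5% of control, 64.5% of bulk and 66.3% of localized cells were called G2/M after thinning. Among all thinned cells these shares were 39.5%, 45.4% and 29.6%. Cluster 6, led by interferon-response genes, held 30.9%, 52.5% and 22.1% of the cells above 25000 UMIs, and 11.9% of all bulk cells. The part of G2/M cells in the bulk excess was not tested. Pairs of like cells, cell fusion and the treatment itself stay open and untested.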

How the results depend on the processing

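The cell calls for cell quality, the settings of cells of 6000 to 20000 UMIs and of the highest Scrublet scores, and most class settings, were chosen after the data were seen. Of the alternative counts of 2-fold genes, 91 lay within 1.5 times the reported count and 23 did not, and of the list medians 1642 stayed close (within the reported median's interval over members), 84 moved and 5 reversed. Only lists that stood apart counted as reversed. Another 52 medians of lists that did not stand apart changed sign, 21 of them under median-of-ratios scaling, such as interferon in localized over control at -0.064 and small nucleolar RNA hosts in bulk over localized at 0.0083. Without a CPM minimum the counts were 137 higher and 64 lower (bulk over control), 210 and 112 (localized over control) and 155 and 115 (bulk over localized), and with a minimum of 50 CPM 10 and 22, 28 and 33, and 24 and 18, because the minimum sets the genes counted. Median-of-ratios scaling gave 55 lower in bulk, and 42 higher and 91 lower in localized over control, with p53 medians of 0.092 and -0.54 and a cholesterol median of -0.40 in localized over control. The largest cluster alone gave 14 higher in bulk and 47 in localized over control and 36 in bulk over localized, with integrated stress response medians of -1.03 in bulk over control and 0.66 in bulk over localized. G1-called cells gave 70 and 121 higher over control and 62 lower in bulk over localized. Cells of 6000 to 20000 UMIs gave 19 higher in bulk over control and 38 in bulk over localized, cholesterol medians of -0.57 and -0.52, and an integrated stress response median of 0.59 in bulk over localized. Means of per-cell CPM gave 0.70 and a cholesterol median of -0.55 for bulk over localized. The interferon median in bulk over control was 1.09 with a pseudocount of 5 CPM and 6.07 with a minimum of 50 CPM (6.31 over localized). Among lists that stood apart, directions reversed for oligodendrocyte precursor markers in bulk over control, at 0.22 in the largest cluster and 0.19 among cells of 6000 to 20000 UMIs, for the unfolded protein response in localized over control, at 0.0046 after free RNA was subtracted, and for astrocyte markers in the largest cluster, at -0.041 in localized over control and 0.076 in bulk over localized. The cause was not tested in these cases. Without thinning, G1 shares were 43.9%, 38.2% and 48.0% in control, bulk and localized electroporation, S shares 15.7%, 14.1% and 21.8%, the bulk G2/M share 47.7%, Ddit3 shares 59.8%, 28.8% and 17.2%, and Cxcl10 shares 1.11%, 48.9% and 2.24%. Over all class settings, including the first naming rule, the oligodendrocyte precursor-like share went from 13.2% to 21.7% in control, 7.11% to 19.4% in bulk and 12.6% to 18.9% in localized electroporation. Astrocyte-like shares went from 8.52% to 17.8%, 10.6% to 18.8% and 14.5% to 42.5% in control, bulk and localized electroporation over the settings with such a class. Integrated stress response medians over control kept their sign in all 19 alternatives. The free RNA alternative took away 10%, while 90% taken from control alone, outside these alternatives, gave 0.23 in bulk. The gene minimum, the mitochondrial limit and the doublet filter removed almost no cells. Alternatives to them therefore tested little, and agreement under them was largely given. Over all alternatives 43 cell quality values stayed within their intervals and 5 did not, all of them bulk values under other cell calls. These were a median of 12178 UMIs and 3402.5 genes with the top 6000 barcodes, and 11496 UMIs, 3298 genes and 9.44% of cells above 25000 UMIs with a minimum of 2000 UMIs. For named genes with an absolute log2 ratio of at least 1, all 3173 alternative ratios kept their sign and 3009 stayed at least 1. With a minimum of 50 CPM no interferon median was had for localized over control, where too few members were left. No paired analysis was possible because each group had 1 library and no test was made.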

Other observations

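Some single genes were chosen after their values were seen. Id1 stood at 137 CPM in control, 77.6 CPM in bulk and 272 CPM in localized electroporation, and Id3 at 338, 332 and 625 CPM. Hes1 had log2 ratios of -0.19 in bulk and -0.69 in localized electroporation over control.

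A set of 6 transfer RNA synthetase genes, also chosen after their values were seen, was compared with no random lists. Sars had a log2 ratio of -1.16 in localized over control, Cars -1.12, Aars -0.80, Gars -0.74, Tars -0.62 and Wars -0.28. In bulk over control the same 6 genes lay between -0.23 and 0.24. Cdkn1a, a p53 target, stood at 563 CPM in control, 786 CPM in bulk and 418 CPM in localized electroporation. Ccl5, a chemokine gene outside the fixed lists, had 1514 UMIs in bulk cells, 2 in control cells and 1 in localized cells.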
